A study of Rattus norvegicus with 9 samples.

How the data were processed

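Total RNA of rat cardiomyocytes was extracted with TRIzol and made into libraries with the NEBNext Ultra II kit, per the labels' protocols. The deposited values are raw counts per Ensembl gene ID, 1 table per library, with the same 30560 IDs in each. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2 1.32.0 were used with the rat build rn6. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. A gene that overlaps another, has an antisense partner or has a near-identical copy can therefore share counts with it.

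Groups and replicate numbers were taken from the sample titles. The tables of the H/R-AS8351 libraries are named with another short code, which the labels do not explain, so that the identity of this group rests on the titles. There were 9 libraries in 3 groups. The total counts in normoxia were 44190772, 54888975 and 37905280, in H/R-DMSO 35711229, 34442733 and 45029140 and in H/R-AS8351 36970569, 47188086 and 43553277. The 10 most abundant genes took between 9.94% and 10.9% of the counts of a library. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.89 and 8.72 over genes with at least 10 counts in the pair, so none was counted as a repeat of another. Between groups it was between 24.9 and 172. Pearson correlations of log2 CPM were between 0.990 and 0.9925 within groups and between 0.9688 and 0.9883 across groups.

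Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its default settings (minimum count 10, minimum total count 15) on the groups, which left 15879 genes with 99.97% of the counts and removed 14681, of which 8599 had a count of 0 in all libraries. Libraries were scaled by TMM, with factors from 0.934 to 0.937 in normoxia, 1.045 to 1.049 in H/R-DMSO and 1.015 to 1.027 in H/R-AS8351. One quasi-likelihood model with a mean per group was fitted to all 9 libraries (glmQLFit, glmQLFTest), so that the groups share one estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 5.04%. CPM values are TMM-normalised. A standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F value. TMM and the related scalings compare each gene with the rest of the RNA in a library, so the RNA content per cell was not measured.

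A gene moved back when it was called after H/R and called in the opposite direction with AS8351. Its count was set beside the overlap of independent lists and beside 20 simulations of unchanged groups with the same library sizes, mean levels and spread. The correlations, with all libraries and with a held-out H/R-DMSO library, were set beside such simulations too. The position of a gene is the difference of its mean CPM in H/R-AS8351 and H/R-DMSO, divided by the difference of normoxia and H/R-DMSO. Its median over genes was taken per H/R-AS8351 library.

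The tests were tried on simulated counts with 200 changed genes. For H/R-DMSO against normoxia, with 15641 genes tested, 52% of the genes changed 1.25-fold were called in the right direction, 84% of those changed 1.5-fold, 78% of those changed 2-fold and 94% of those changed 4-fold, and 5.52% of the calls were false. For H/R-AS8351 against H/R-DMSO, with 15645 genes tested, these were 50%, 84%, 74% and 100%, with 1.91% false calls. For H/R-AS8351 against normoxia, with 15650 genes tested, they were 54%, 84%, 74% and 98%, with 2.52% false calls. A simulated position of 30% came back as 29.4% for genes that fell and 32.8% for genes that rose, with 15698 genes tested.

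The comparisons, their tests and most alternatives were set before the data were examined. The rule for named genes took Kdm5b and Brinp2, then, for each comparison, the 6 genes with the largest increase and the 6 with the largest decrease among called genes with a mean of at least 5 CPM, groups that do not overlap and a settled gene symbol, plus members of gene lists. The files hold only Ensembl IDs, and the rat gene table used here, of assembly GRCr8 with 47357 genes, lists an Ensembl ID for 0 of them. So 0 IDs could be given a symbol, and Kdm5b, Brinp2, the 38 gene lists written in advance and the cell type markers among them are not analysed here. Checks of GC content and gene length were not possible for the same reason. The 4 IDs named were chosen by the same rule without its symbol criterion, limited to 2 per direction and to the comparison of H/R-DMSO with normoxia, after the values were seen.

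The alternatives were RLE and upper-quartile scaling, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with limma 3.58.1, a fit of the 2 groups compared alone, the replicate number as a block, a minimum of 1 for the size of the log2 fold change, and each library left out in turn. For the genes moved back and for the correlation, the H/R-DMSO libraries were also held out in turn. Scaling to the total count, the positions, the count of genes outside both other groups, the alternatives for counts per direction and size, and the tests of a mixture of cells were added after seeing the data.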

Results

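RNA was measured in 9 libraries of rat cardiomyocytes, 3 per group. Cardiomyocytes are the contracting cells of the heart. The first group stayed in normoxia. The second went through hypoxia and reoxygenation (H/R), a culture model of a heart that loses and then regains its blood supply: 6 h at 0.1% oxygen in medium without glucose and pyruvate, then 12 h at 21% oxygen in standard medium, with the solvent DMSO (H/R-DMSO). The third went through the same steps with 0.5 µM AS8351 added for the reoxygenation (H/R-AS8351). The labels call AS8351 an inhibitor of Kdm5b, a histone lysine demethylase. The libraries held between 34442733 and 54888975 counts, and between 18254 and 18912 genes had at least 1 count in a library. After removal of genes with few counts, 15879 genes were tested. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

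The files give Ensembl gene IDs and do not pair them with gene names, and 0 of the 30560 IDs matched the rat gene table at hand. Kdm5b and Brinp2, the genes of the series title, therefore carry no value here, and the genes are described by how they moved between the groups. At most 2 IDs that rose and 2 that fell are named.

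The 3 groups lay apart in a principal component analysis of the log2 CPM, the counts scaled to a common library size. The first component held 52.9% of the variance and separated normoxia at -44.2 ± 2.13 (SD, n = 3) from H/R-DMSO at 35.4 ± 0.719, with H/R-AS8351 between them at 8.77 ± 1.07. The second component held 10.4% of the variance. H/R-AS8351 stood at 20.2 ± 1.85 on it, above normoxia at -6.79 ± 0.553 and H/R-DMSO at -13.4 ± 4.10.

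**Figure D1:**
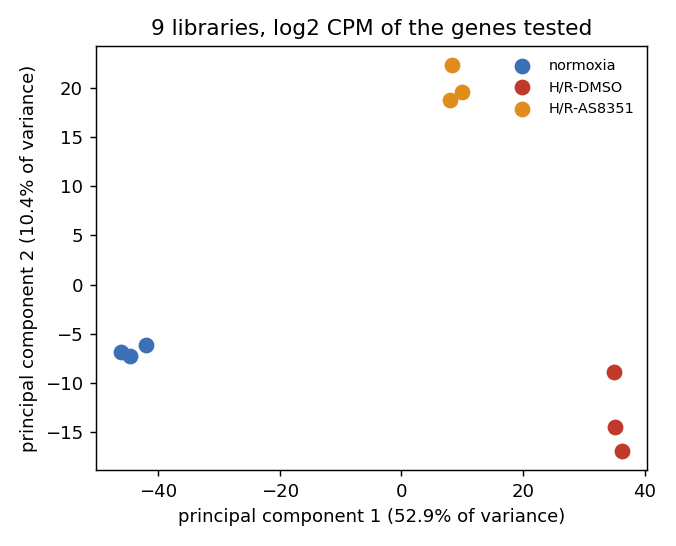
Principal component 1 (x axis, arbitrary units, 52.9% of the variance) against principal component 2 (y axis, arbitrary units, 10.4%) for the 9 libraries, 1 point per library coloured by group. H/R-AS8351 lies between the other groups on the x axis and above both on the y axis.

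The comparison of H/R-DMSO with normoxia asks what H/R, with the solvent, did to the cells' RNA. After H/R, 4361 genes rose and 4003 fell, which is 52.7% of the genes tested (edgeR quasi-likelihood test, adjusted p below 0.05). Most of the changes were small. The median log2 fold change was 0.38 among the genes that rose and -0.43 among those that fell, and 711 genes rose and 691 fell at least 2-fold. At least 4-fold changes were seen for 156 genes that rose and 173 that fell. Many of the large changes were in genes of low abundance: with a mean of at least 1 CPM, 438 genes rose and 499 fell at least 2-fold, and 63 rose and 109 fell at least 4-fold. The genes that fell were the more abundant group: they held 54.3% ± 0.128 (SD, n = 3) of the counts in normoxia and 42.3% ± 0.397 after H/R. The genes that rose went from 20.9% ± 0.0653 to 29.8% ± 0.192 of the counts.

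Among genes with a mean of at least 5 CPM, ENSRNOG00000019120 had the largest increase after H/R. It rose from 0.232 ± 0.0496 CPM (SD, n = 3) to 11.7 ± 1.67 CPM, a log2 fold change of 5.67 (SE 0.21, adjusted p = 8.01e-26 by edgeR), and rested on 9 to 11 counts per normoxia library. ENSRNOG00000029911 followed, from 13.3 ± 0.597 to 204 ± 10.4 CPM, a log2 fold change of 3.94 (SE 0.05, adjusted p = 3.88e-41 by edgeR). The largest decrease was that of ENSRNOG00000017766, from 98.3 ± 1.12 to 2.79 ± 0.525 CPM, a log2 fold change of -5.16 (SE 0.08, adjusted p = 7.95e-39 by edgeR). ENSRNOG00000068340 fell from 20.5 ± 2.15 to 0.908 ± 0.0392 CPM, a log2 fold change of -4.49 (SE 0.14, adjusted p = 4.13e-28 by edgeR).

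The CPM ranges of the 2 groups did not overlap for 94.3% of the called genes and 57.5% of all genes tested, where chance gives 10%. The split between directions rested on the scaling. Scaled to the total count alone, 7282 genes were higher and 2515 lower after H/R, so that 74.3% of the called genes were higher, against 52.1% in the main result, as that scaling moved the median of all genes by 0.16 on the log2 scale. The labels do not say whether the normoxia cells received DMSO, so this comparison covers low oxygen, the change of medium, reoxygenation and possibly the solvent together.

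The comparison of H/R-AS8351 with H/R-DMSO asks what the compound did to cells that went through the same H/R. With AS8351, 2088 genes were higher and 1583 lower, 23.1% of the genes tested (edgeR quasi-likelihood test, adjusted p below 0.05). The larger changes were mostly increases: 193 genes rose and 24 fell at least 2-fold, and 136 rose and 8 fell when a mean of at least 1 CPM was required. For the same share of the way back in CPM, genes that fell after H/R change more in log2 than genes that rose as much. This split alone therefore does not show a stronger action on the genes that fell after H/R. The median log2 fold change was 0.30 among the genes that rose and -0.23 among those that fell. Since the spread between libraries may be technical, changes of this size cannot be told from differences between cultures. All 4 named genes moved against their change after H/R. ENSRNOG00000017766 rose to 36.0 ± 1.76 CPM (SD, n = 3), a log2 fold change of 3.71 (SE 0.08, adjusted p = 5.77e-32 by edgeR), and ENSRNOG00000068340 to 7.87 ± 0.942 CPM, a log2 fold change of 3.11 (SE 0.15, adjusted p = 1.64e-20 by edgeR). ENSRNOG00000019120 fell to 7.18 ± 0.902 CPM, a log2 fold change of -0.70 (SE 0.12, adjusted p = 2.65e-05 by edgeR), and ENSRNOG00000029911 to 132 ± 2.43 CPM, a log2 fold change of -0.63 (SE 0.04, adjusted p = 1.16e-15 by edgeR).

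The CPM ranges of the 2 groups did not overlap for 94.4% of the called genes and 35.0% of all genes tested, where chance gives 10%. The number of lower genes was 1042 without replicate 2 of H/R-AS8351. Scaled to the total count alone, 1656 genes were higher and 2383 lower, so that 41.0% of the called genes were higher with AS8351, against 56.9% in the main result.

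**Figure D2:**
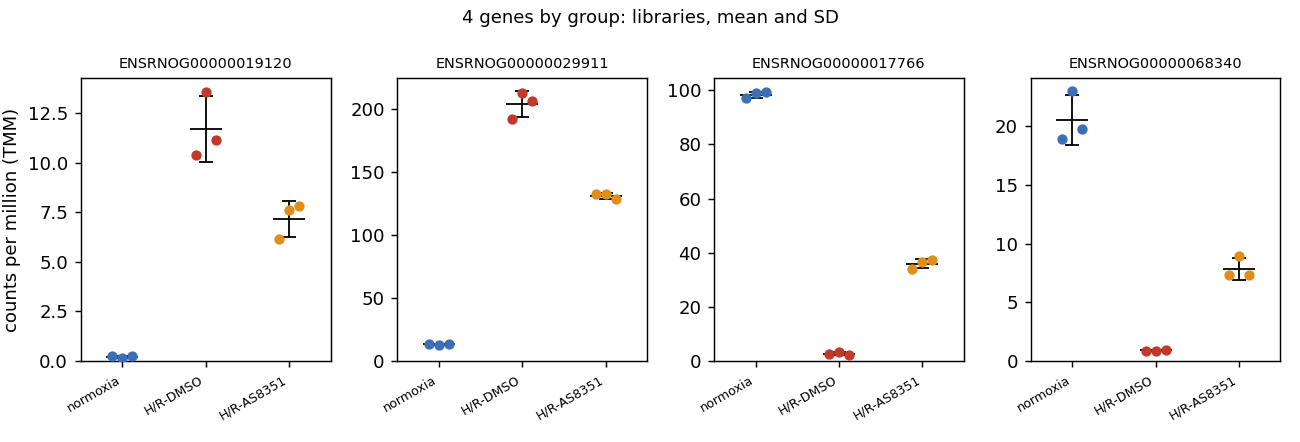
TMM-normalised CPM (y axis, linear, a separate scale per gene) of the 4 named genes in the 3 groups (x axis). Points are libraries, the long bar is the mean and the error bars are the SD (n = 3). Every H/R-AS8351 library lies between the other groups, for example at 36.0 CPM on average for ENSRNOG00000017766, against 98.3 in normoxia and 2.79 in H/R-DMSO.

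The series title speaks of improving the injury by inhibiting Kdm5b, so the genes changed after H/R were followed into the H/R-AS8351 libraries. Of the 3671 genes changed with AS8351, 3075 (83.8%) had changed the opposite way after H/R, and are called moved back here. Raised and lowered name differences from the H/R-DMSO libraries. If the libraries of a group shared a culture, the compound and the culture cannot be told apart. Among the 4003 genes that fell after H/R, 1789 (44.7%) were raised in the H/R-AS8351 libraries. Of these, 1234 were still lower than in normoxia and 543 were not called different from it. Among the 4361 genes that rose after H/R, 1286 (29.5%) were lowered. Of these, 634 were still higher than in normoxia and 634 were not called different from it. Only 116 genes moved further in the direction of H/R, 46 of them down and 70 up. A further 480 genes changed with AS8351 and were not called after H/R, 229 higher and 251 lower. These were 147 and 118 without replicate 2 of H/R-AS8351, and the lower ones were 143 without replicate 3.

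Independent lists of these sizes would share 526 genes that fell and were raised and 435 that rose and were lowered, and would give 399 that fell further and 573 that rose further. Both comparisons use the same H/R-DMSO libraries with opposite sign, which by itself favours opposite directions. In 20 simulations of unchanged groups with these libraries, at most 1 gene was called in any comparison. With so few calls, they cannot show how much the shared libraries add where many genes changed. Part of the excess over independent lists may still come from the shared libraries, since the 3 H/R-DMSO libraries cannot be split into parts of 2. With genes called from 2 of the H/R-DMSO libraries and the move measured against the left-out library, between 76.0% and 81.5% of them lay on the normoxia side, against 85.8% with all 3. Scaled to the total count alone, the order of the counts turned: 1321 genes that fell were raised, 788 of them still below normoxia, and 2199 that rose were lowered, 1461 of them still above it. The share of genes moved back stayed higher among those that fell (52.5%) than among those that rose (30.2%). Under that scaling 24 genes fell further with AS8351, and 160 genes were lower with AS8351 and not called after H/R.

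Across the 15879 genes, the log2 fold changes of H/R and of AS8351 had a Pearson correlation of -0.67 and a Spearman correlation of -0.64. Genes are not independent replicates, so no p-value is given. Unchanged groups that share the H/R-DMSO libraries gave a Pearson correlation of -0.50 ± 0.013 (SD over 20 simulations). The covariance was -0.163, against a simulated -0.0185, a difference of -0.145. With the left-out H/R-DMSO library for the AS8351 change, the Pearson correlation was between -0.50 and -0.46 and the covariance between -0.125 and -0.121. These changes share no H/R-DMSO library, and unchanged groups simulated in the same way gave Pearson correlations between -0.02 and 0.04 (20 simulations, each library left out in turn). The simulated libraries were drawn independently, so a deviation common to all libraries of a group, as from a shared culture, was not tested.

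**Figure D3:**
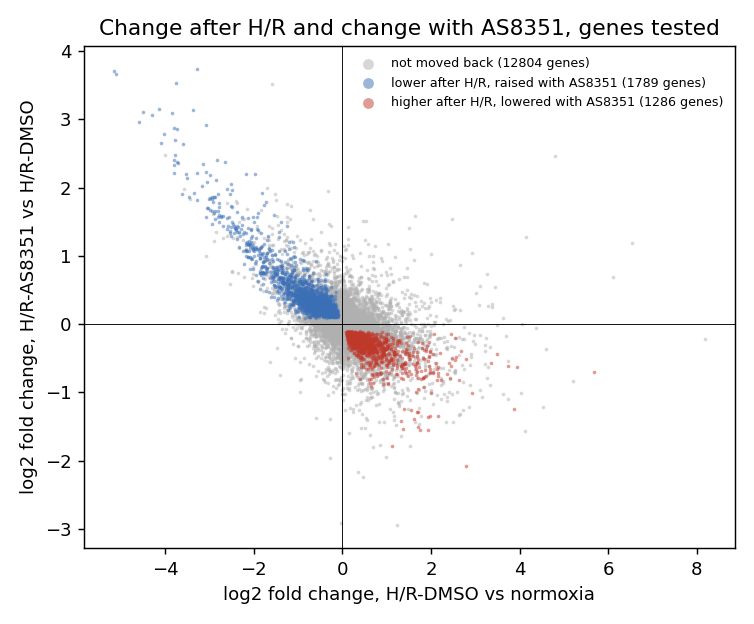
Log2 fold change after H/R (x axis, H/R-DMSO against normoxia) and with AS8351 (y axis, H/R-AS8351 against H/R-DMSO), 1 point per gene tested. The 1789 genes that fell and were raised lie at the upper left in blue, the 1286 that rose and were lowered at the lower right in red, and the remaining genes are grey.

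The share of genes moved back grew with the size of the change for genes that fell after H/R. It was 16.7% of the 959 genes with a log2 change smaller than 0.25 and 80.3% of the 173 genes that fell at least 4-fold. For genes that rose it was 24.7% of the 1256 genes with the smallest changes, 35.1% of the 917 genes with a log2 change between 0.5 and 1, and 21.2% of the 156 genes that rose at least 4-fold. Genes of low abundance set that last decrease: with a mean of at least 1 CPM, the share grew with size in both directions, from 26.3% of 1326 genes to 52.4% of 63 genes for those that rose and from 17.8% of 978 genes to 98.2% of 109 genes for those that fell. A gene had to be called with AS8351 to count, and the return of a larger change is easier to call. The median gene that fell at least 2-fold lay 35.3% of the way to normoxia in CPM, and at least 4-fold 36.3%. For genes that rose it was 33.8% and 31.1%. The growing share therefore does not show a fuller return of larger changes. No position was taken for changes under 2-fold. On the log2 CPM scale, genes that fell at least 2-fold stood at 50.9% and at least 4-fold at 58.1%. Genes that rose stood there at 21.6% and 15.4%.

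**Figure D4:**
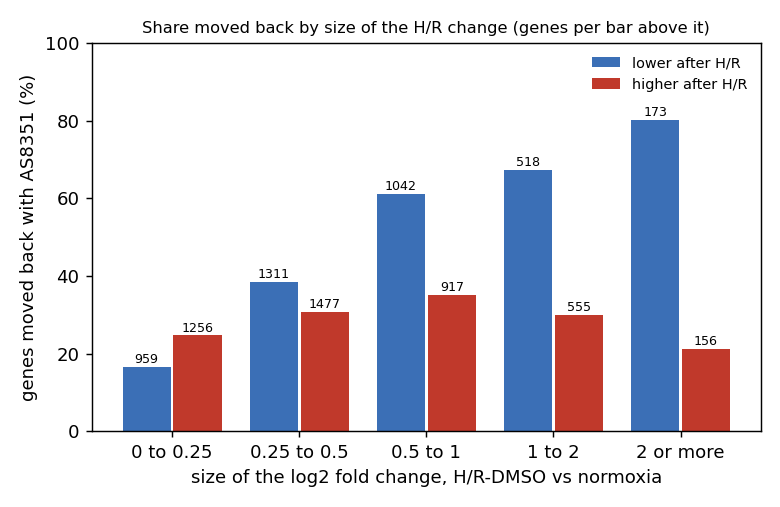
Share of genes moved back with AS8351 (y axis, percent) by the size of their log2 fold change after H/R (x axis), for genes lower (blue) and higher (red) after H/R. The number above each bar is the number of genes, and the blue bars go from 16.7% to 80.3%.

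The place of the H/R-AS8351 libraries between the other groups was measured on the linear CPM scale, with H/R-DMSO at 0% and normoxia at 100%. For the 691 genes that fell at least 2-fold after H/R, the median gene stood at 35.3% ± 1.61 (SD over 3 libraries), with an interquartile range over genes from 27.5% to 45.1%. For the 711 genes that rose at least 2-fold, it stood at 33.8% ± 1.37, with a wider interquartile range from 14.3% to 51.5%. Almost all of the genes that fell (99.3%) lay on the normoxia side of H/R-DMSO, and 85.0% of those that rose. These genes were chosen with the same normoxia and H/R-DMSO libraries. With libraries left out of the choice, the position was between 34.2% and 35.8% for genes that fell and between 29.6% and 32.3% for genes that rose. The 4 named genes stood at 39.4% for ENSRNOG00000019120, 38.0% for ENSRNOG00000029911, 34.8% for ENSRNOG00000017766 and 35.5% for ENSRNOG00000068340.

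The comparison of H/R-AS8351 with normoxia asks what still differed from unstressed cells once the compound was given. Here 3127 genes were higher and 3130 lower than in normoxia, 39.4% of the genes tested (edgeR quasi-likelihood test, adjusted p below 0.05). Large decreases had become few: 178 genes were lower at least 2-fold, against 691 for H/R-DMSO. Large increases were more numerous, with 473 genes higher at least 2-fold, against 711 for H/R-DMSO. With a mean of at least 1 CPM the counts were 118 lower and 293 higher, against 499 and 438 for H/R-DMSO, and scaled to the total count 111 were lower. For the same share of the way back in CPM, genes that fell after H/R also end nearer to normoxia in log2. This difference alone therefore does not show a fuller return of the genes that fell. The genes that fell after H/R held 46.5% ± 0.398 (SD, n = 3) of the counts with AS8351, between the 42.3% of H/R-DMSO and the 54.3% of normoxia. The genes that rose held 26.6% ± 0.234, between 29.8% and 20.9%.

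ENSRNOG00000017766 was still below normoxia by a log2 fold change of -1.45 (SE 0.06, adjusted p = 8.65e-24 by edgeR), and ENSRNOG00000068340 by -1.38 (SE 0.10, adjusted p = 7.23e-15 by edgeR). ENSRNOG00000019120 was above it by 4.97 (SE 0.21, adjusted p = 1.25e-22 by edgeR) and ENSRNOG00000029911 by 3.31 (SE 0.05, adjusted p = 1.16e-37 by edgeR). The CPM ranges of the 2 groups did not overlap for 95.8% of the called genes and 48.9% of all genes tested, where chance gives 10%. Scaled to the total count alone, 5875 genes were higher and 1786 lower, so that 76.7% of the called genes were higher than in normoxia, against 49.98% in the main result, with the median of all genes moved by 0.12 on the log2 scale.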

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

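Scaling to the total count, the positions with their alternatives, the count of genes outside both other groups and the counts per direction and size were chosen after seeing the data. The 4 named genes kept their direction and side of the threshold in all 180 values under alternatives. They were chosen for large called changes of H/R-DMSO against normoxia, so their stability in that comparison follows largely from the choice. Of 50 counts of genes, over both directions together, under alternatives other than left-out libraries, 45 were within 1.5 times of the main count. The other 5 came from the minimum of 1 for the log2 fold change, which by its construction calls fewer genes: 1402 after H/R, 217 with AS8351, 651 for H/R-AS8351 against normoxia, 201 moved back and 10 outside both other groups. Of the 201, 183 had fallen and were raised (26.5% of those that fell) and 18 had risen and were lowered (2.53% of those that rose). With each library left out, the 36 counts over both directions stayed within 1.5 times, while without replicate 2 of H/R-AS8351 the genes lower with AS8351 went from 1583 to 1042 and those lower than both other groups from 182 to 113. The counts over both directions ranged from 7635 to 7928 genes after H/R, from 2744 to 3528 with AS8351, from 5459 to 5670 for H/R-AS8351 against normoxia, from 2390 to 2939 moved back and from 267 to 404 outside both other groups. Replicate numbers gave no clear pairing of the libraries: deviations from the group means correlated between -0.023 and 0.042 for libraries of the same number and between -0.045 and 0.026 for the others. Such overlap does not exclude a weak pairing. With the replicate block, 8539, 3940 and 6468 genes were called in the 3 comparisons, 3273 were moved back, 447 lay outside both other groups, and the correlation was -0.67.

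The correlation of the H/R and AS8351 changes stayed negative under every alternative, but shared H/R-DMSO libraries alone gave -0.50 in the main setting. Only held-out ones test its sign, and they cannot show a deviation common to all 3 H/R-DMSO libraries. The values of -0.52 and -0.53 lie near -0.50. The size of the correlation moved by more than the spread between libraries under several alternatives. It was -0.52 with no filter, -0.74 with a mean of at least 1 CPM, -0.53 with DESeq2, which here tested genes without the filter, -0.70 with the 2 groups alone and -0.81 over genes with a mean of at least 10 CPM. With left-out libraries it ranged from -0.68 to -0.62. With held-out H/R-DMSO libraries 1, 2 and 3 it was -0.46, -0.46 and -0.50, and 76.0%, 80.5% and 81.5% of the H/R-changed genes lay toward normoxia, against 85.8%. These held-out values use 1 H/R-DMSO library in place of 3. The position of genes that fell moved from 35.3% to 39.3% with total-count scaling and to 50.9% on the log2 CPM scale. That of genes that rose moved from 33.8% to 31.1% for changes of at least 4-fold, to 21.6% on the log2 CPM scale and to between 29.6% and 32.3% with held-out libraries. Apart from the log2 scale, which changes the measure itself, the cause was not tested. Those for Kdm5b, Brinp2 and the gene lists were not run, as no ID had a symbol. With the depth, spread and 3 libraries per group of these data, 50% of the simulated changes of the smallest size tried were called in the comparison of H/R-AS8351 with H/R-DMSO. How much of this depth alone sets was not tested.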

Other observations

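The tests of a mixture of cells were chosen only after the counts of the 3 comparisons had been seen, and the test on genes that rose, as well as the reading of the test on genes that fell as open, only after their own values had been seen. Some genes in the H/R-AS8351 libraries lay outside both other groups. In H/R-AS8351, 210 genes were higher and 182 lower than in both normoxia and H/R-DMSO, together 2.47% of the genes tested (edgeR, adjusted p below 0.05 in both comparisons). Without replicate 2 of H/R-AS8351 these were 154 and 113 genes, and with total-count scaling 287 and 123. The changes were small, with a median log2 fold change against H/R-DMSO of 0.26 for the higher and -0.21 for the lower genes, and 8 and 2 of them reached 2-fold. Most had not been called after H/R (128 of the higher and 118 of the lower genes), while 70 of the higher genes had risen after H/R and 46 of the lower had fallen. As the spread between libraries may be technical, changes this small cannot be told from differences between cultures. All genes called with AS8351 had medians nearly as small, 0.30 for the higher and -0.23 for the lower genes. The same limit therefore holds for many of them, also among the genes moved back.

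The 2 directions lay far apart on the log2 scale and near each other on the linear one. On the log2 CPM scale, the H/R-AS8351 libraries stood at 50.9% ± 2.34 (SD over 3 libraries) of the way from H/R-DMSO to normoxia for genes that fell at least 2-fold and at 21.6% ± 1.18 for genes that rose. On the linear CPM scale they stood at 35.3% ± 1.61 and 33.8% ± 1.37, and with libraries held out of the choice of genes at 34.2% to 35.8% and at 29.6% to 32.3%, close to each other but not equal.

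The pattern weighed here is that genes changed after H/R lay back toward normoxia in the H/R-AS8351 libraries. Chance values of single H/R-DMSO libraries, shared by the comparisons, are argued against by the held-out libraries. Against these, at least 76.0% of the H/R-changed genes lay toward normoxia. A deviation common to all 3 H/R-DMSO libraries, as from a shared culture, would also be in the left-out library and was not tested. The choice among the scalings tried is argued against as the source of the pattern by the other 3. These left at least 73.8% of the main count moved back in either direction, though total-count scaling turned the order of the directions. RLE and upper-quartile scaling lie close to TMM here. They moved the median log2 fold change after H/R by -0.018 and 0.010, against 0.16 for total-count scaling, which is thus the main test. All of these scalings are relative to the RNA of a library, so a change of RNA content per cell was not tested. RNA of normoxia-like and H/R-DMSO-like cells in one fixed proportion is argued against as the account of all genes by the 2.47% called outside both other groups. A simulated mixture of 30% gave 9 such genes of 15698. For the 156 genes that rose at least 4-fold it is argued against by the SD of their positions, 2.08 times the root mean square standard error. This ratio was over the limit of 1.5 and the highest ratio of 1.04 in 20 simulated mixtures. It was 5.61 for the 61 of these genes with a mean of at least 1 CPM. From the median absolute deviation and the median standard error, which a few far genes move less, the ratios were 1.56 and 2.96. Such subsets were taken from genes called in the main result, so their sizes differ slightly from those of the new fit with that minimum. These calls and standard errors rest on a spread between libraries that may be technical, so a mixture may be argued against too readily. For the 173 genes that fell at least 4-fold it stays open: the ratio was 1.21, under the limit of 1.5, by which alone a mixture would have been taken to account for them, but above the highest of 1.10 in 20 simulated mixtures, and 15.6% of the genes lay over 2 standard errors from the median, against at most 8.09% in the simulations (for the 110 with a mean of at least 1 CPM the ratio was 1.39, or 1.59 from the median absolute deviation and the median standard error, and 20.9% lay over 2 standard errors). So a share of cells that escaped the H/R response, a partial response in every cell, or both may lie behind the return of the genes that fell, and bulk RNA with no named marker genes cannot separate them.

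Each comparison was set against other splits of its 6 libraries, of which 3 against 3 makes 10 in all, too few for a share under 0.05. In each of the 4 cases 1 split, the real one, gave as many genes. Every other split puts libraries of both groups on each side, so the group difference enters the spread and lowers the calls. The low counts of the other splits follow largely from this and are no measure of chance. Where 0 genes are called with AS8351, 0 can be moved back. For H/R-DMSO against normoxia the real split called 8364 genes and the highest of the others 0 (edgeR, with 9091 and 366 genes at an unadjusted p under 0.05). For H/R-AS8351 against H/R-DMSO the counts were 3671 and 0 (5294 and 1114 unadjusted), for H/R-AS8351 against normoxia 6257 and 0 (7369 and 456 unadjusted), and for genes moved back 3075 and 0 (4158 and 636 unadjusted).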
